A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

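Poly(A) RNA of budding yeast (Saccharomyces cerevisiae) was measured by strand-specific sequencing in 12 libraries, 3 in each of 4 groups. The groups were a reference strain and a strain labelled with a histone H3 S10D construct, each after 3 hours with ethanol (EtOH) or with estradiol (E2). Per the labels, each library was made from 400 ng of total RNA with 12 PCR cycles. The deposited table holds counts, whole numbers of reads per annotated gene, for 7127 features and with a column per library. The submitters' processing notes list bcl2fastq 2.20.0.422, cutadapt 1.10, STAR 2.5.3a, HTSeq 0.6.1p1 and the genome builds R64 and sacCer3. They do not state the role of each tool, the counting mode, the strand setting or the annotation release.

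Features were placed on build R64 by locus tag (6047 features) or by symbol (41 features). The 1039 features without a match held at most 0.481% of a library's counts and were kept in the gene tests but not in the chromosome values. Libraries held between 9362173 and 11806239 counts. Features were tested where edgeR's filterByExpr kept them (minimum count 10, minimum total count 15), which left 5990, of which 5664 were nuclear features with a position. The common biological coefficient of variation was 6.31%. Intervals of ratios cover counting error alone, because they use counts pooled over 3 libraries and leave out the spread between libraries. PCR reads without molecular identifiers are not independent molecules, so these intervals may be too narrow even for counting error. The 95% intervals of ratios near 0 counts are exact (Clopper-Pearson).

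Counts were normalized by TMM and tested with edgeR 4.0.16 (quasi-likelihood test, robust fit, 2-sided, R 4.3.3) in a model of 4 group means over all 12 libraries, which gave 8 residual degrees of freedom. The comparisons were E2 against EtOH in the reference strain, the same in the S10D-labelled strain, the difference of these responses (S10D-labelled minus reference), and the S10D-labelled against the reference strain in EtOH. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes are log2 with the standard error (SE) of the fit, and levels are TMM-scaled CPM with the standard deviation (SD) of 3 libraries.

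The centromere between lox sites lies on chromosome IV, so the median log2 fold change of its genes minus that of all other nuclear genes was computed for each comparison. Sets were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and again with an estimated correlation. The 16 chromosomes were adjusted together. Chromosome IV among called genes was tested with Fisher's exact test against all nuclear genes tested, which treats genes as independent. The share of nuclear counts on chromosome IV was compared by exact 2-sided permutation of 3 libraries against 3 (smallest possible p 0.1) and, for the difference of responses, over all 400 relabellings within strains. In addition, 31 gene lists fixed by name and 4 fixed by position were tested with camera, with 1 adjustment over the 140 tests of lists and comparisons. Members of each list were counted as called over all genes and as called when adjusted over the list alone.

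The gene lists, the tests of the comparisons, most alternatives and the rule for naming genes were fixed before the data were examined. Some tests of explanations were chosen later, as stated where they are reported. The rule took, among called genes with a mean of at least 10 CPM and, in comparisons of groups, no overlap between the libraries of both groups, the 10 largest and 10 smallest fold changes of each comparison. For both E2 comparisons it added the 5 largest and 5 smallest on chromosome IV, for each list described up to 4 members with the largest absolute change, and all members of the galactose list. Genes altered in the genotype labels were read as counts per library. Not every gene that this rule named is reported here.

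Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, TMM without chromosome IV, no filter, a mean of at least 10 CPM, an absolute log2 fold change of at least 1, the replicate number as a block, a fit of the 6 libraries compared, and each library left out in turn. For chromosome IV and the lists, they were the estimated correlation, shares without ribosomal protein genes or without the 50 features with most counts, and lists without their chromosome IV members. Fits without reference EtOH replicate 3 for the S10D-labelled response, the lists and chromosome IV among called genes, and the chromosome IV median with an estimated correlation, were added after the data had been seen.

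The pipeline was tested on simulated data with changes put into 200 genes of the reference comparison. With edgeR, 28 of 49 tested genes changed 1.25-fold were recovered, 44 of 50 changed 1.5-fold, 46 of 49 changed 2-fold and 50 of 50 changed 4-fold, with 8 calls among 5746 unchanged genes. A chromosome IV shift of 0.1 put into the simulation was recovered as 0.10. All simulated libraries shared the spread of each gene, genes were drawn independently and no library stood apart. The simulation therefore does not test how unequal spread or correlated genes affect the calls. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 and drawn with matplotlib 3.10.9.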

Results

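The 12 libraries came from yeast strains of mating type a. Both strains are labelled as carrying the centromere of chromosome IV (CEN4, chromosome IV 449711 to 449821, build R64) between lox sites, together with a Cre recombinase fused to an estrogen-binding domain. Estradiol switches on such a recombinase, which can then cut out the DNA between the lox sites. The reference strain is labelled with deletion alleles of HIS3, LEU2, URA3 and MET17, and with LEU2 as the marker of the recombinase gene. The other strain, called S10D-labelled here, is labelled with a construct at HHT2 and HHF2 that carries histone H3 with aspartate in place of serine at residue 10. Aspartate there is commonly used to stand in for the phosphorylated serine of mitotic chromosomes. Each strain was given ethanol (EtOH) or estradiol (E2) for 3 hours, with 3 libraries per group and 9362173 to 11806239 counts per library. No library came from a strain whose CEN4 lacks lox sites, so E2 or Cre alone is not separated from the loss of CEN4, and the excision itself is not measured by these counts. The labels do not say whether the libraries of a group came from separate cultures, so each p measures the spread between these libraries.

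Marker genes were read against the genotype labels. URA3 had 0 to 5 counts in each reference library and 1212 to 1529 in each S10D-labelled library, and MET17 had 11 to 23 against 12171 to 16066, and the reference label gives both as deleted. HIS3 and LEU2, listed there as deleted too, had 627 to 882 and 2813 to 4244 counts in each reference library, against 4810 to 6064 and 1861 to 2414 in the S10D-labelled. HHF2 and HHT2, the histone genes replaced by the construct, were lower in the S10D-labelled strain (log2 fold changes -4.46 ± 0.10 and -1.80 ± 0.05, SE, n = 3 per group). Their paralogs HHF1 and HHT1 were higher (1.19 ± 0.06 and 0.80 ± 0.08), and reads shared between such paralogs leave these values uncertain. BAR1, the protease that degrades alpha factor, had 3162 to 3787 counts in each S10D-labelled library, although the label lists it as deleted. It had 6829 to 9265 in each reference library and was lower in the S10D-labelled strain (-1.22 ± 0.06). Of the other genes altered in the genotype labels, ADE1 was lower there (-2.22 ± 0.06), and TRP1 (1.61 ± 0.06) and LYS4 (1.21 ± 0.07) were higher. The histone residue itself cannot be read from gene counts.

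Reference EtOH replicate 3 stood apart from its group. The chi-square per degree of freedom of its pairs with replicates 1 and 2 was 31.5 and 32.5, against 1.4 to 5 for the other 10 pairs within groups. In this library the median gene of the general stress list lay 0.15 (log2) above its group mean, core histone genes 0.13 above and ribosomal protein genes 0.04 above. The signal recognition particle RNA SCR1 had 204 CPM there against 84.6 and 75.2 in replicates 1 and 2, and the mitochondrial 21S_RRNA had 153.0 CPM against 28.7 and 44.3.

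In the reference strain, E2 against EtOH asks how gene expression changes when CEN4 can be excised. Genes of varied roles were among those that rose most. SHC1, a chitin synthase regulator of sporulation and alkaline growth (YER096W, V 351698 to 353236), went from 13.5 ± 1.30 to 76.5 ± 3.72 CPM (SD, n = 3), a log2 fold change of 2.49 ± 0.08 (SE). CYC7, the cytochrome c isoform of low oxygen, rose by 2.14 ± 0.11, HXT5, a hexose transporter of slow growth, by 1.83 ± 0.09, the proline permease PUT4 by 1.65 ± 0.12 and the cytosolic catalase CTT1 by 1.64 ± 0.05. Among the genes that fell, SPL2 changed by -1.26 ± 0.11, the transcription factor gene HMS2 by -1.15 ± 0.06 and the hexose transporter genes HXT6 and HXT7, which are near-identical in sequence, by -1.11 ± 0.16 and -0.95 ± 0.09.

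With edgeR, 2671 of 5990 genes were called in the reference strain, 1342 higher and 1329 lower, and 129 of them changed at least 2-fold (117 higher, 12 lower). The libraries of both groups did not overlap for 2915 genes (48.7%), where chance gives 10%. Adjusted p values of the genes above lay between 7.57e-11 (SHC1) and 0.000156 (HXT6). The mitochondrial 21S_RRNA was called lower (-1.86 ± 0.68, adjusted p = 0.04999). It stood at -0.80 and was no longer called without reference EtOH replicate 3 (adjusted p = 0.264, and 0.0192 to 0.264 over the alternatives), nor without any of the 3 E2 libraries (adjusted p up to 0.129). RPL38 was called lower at -1.32 ± 0.39 and stood at -0.56 ± 0.04 without that library, while it was not called without E2 replicate 2 or 3 (adjusted p up to 0.0572, and 1.52e-11 to 0.0583 over the alternatives).

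Ribosomal protein genes fell together in the reference strain, with 124 of 137 lower, none higher and 13 not called (128 lower when adjusted over the list alone). Their median was -0.54, and RPL42B (-1.22 ± 0.17) and RPS12 (-1.14 ± 0.18) were among the lowest. In EtOH both of these genes were highest in replicate 3 (RPL42B 2055.7 CPM against 1537.5 and 1153.3, RPS12 4389.3 against 2796 and 2434.8). Camera gave an adjusted p of 4.65e-56, and an adjusted p of 0.04998, just under the threshold, with an estimated correlation. Of 32 general stress genes, 25 rose, 3 fell and 4 were not called (26 and 3 adjusted over the list alone), with a median of 0.79 (adjusted p = 3.20e-34, and 0.00963 with an estimated correlation). PHM7 rose by 1.60 ± 0.06 and the phosphogluconolactonase gene SOL4 by 1.39 ± 0.10. Of 20 sulfur and methionine genes, 16 rose and 4 were not called (16 adjusted over the list alone), with a median of 0.51 (adjusted p = 2.33e-12, and 0.0330 with an estimated correlation). MET13 rose by 1.16 ± 0.09 and MET2 by 1.09 ± 0.06. Of 16 DNA damage response genes, 11 rose and 5 were not called (11 adjusted over the list alone), including the ribonucleotide reductase gene RNR3 (0.92 ± 0.10) and RAD16 (0.77 ± 0.07). This list had a median of 0.33 (adjusted p = 0.000467, and 0.0461 with an estimated correlation). Daughter-cell genes of the M/G1 boundary fell, with 9 of 13 lower, 1 higher and 3 not called (10 and 1 adjusted over the list alone), a median of -0.27 and NIS1 (-0.68 ± 0.05), DSE2 (-0.61 ± 0.04) and the chitinase gene CTS1 (-0.51 ± 0.04) among them. Camera gave this list an adjusted p of 2.79e-05, and 0.0481 with an estimated correlation.

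Other lists were called in the reference strain with the preset correlation alone. Heat shock chaperone genes had 15 of 21 members higher and 6 not called (16 higher adjusted over the list alone), with HSP82 at 1.26 ± 0.05, SSA4 at 1.19 ± 0.06 and HSP104 at 1.05 ± 0.06, a median of 0.51 and an adjusted p of 7.57e-15 (adjusted p = 0.126 with an estimated correlation). Core histone genes had 7 of 8 members lower and 1 not called (7 adjusted over the list alone), with HTA2 at -0.68 ± 0.07, a median of -0.53 and an adjusted p of 9.52e-05 (adjusted p = 0.312 with an estimated correlation). Drug efflux genes had 6 of 12 members higher and 6 not called (8 higher adjusted over the list alone), with SNQ2 at 0.80 ± 0.06, and a median of 0.31 that stood at 0.15 without reference EtOH replicate 3 (adjusted p = 0.00273, and adjusted p = 0.333 with an estimated correlation). Purine synthesis genes had 7 of 10 members lower and 3 not called (7 adjusted over the list alone). ADE17 was at -0.53 ± 0.06 and the list median was -0.30 (adjusted p = 0.00453, and adjusted p = 0.375 with an estimated correlation). Genes of a cells and the pheromone response had 14 of 23 members lower, 2 higher and 7 not called (the same numbers adjusted over the list alone), with the agglutinin gene AGA1 at -0.89 ± 0.09, the pheromone gene MFA1 at -0.79 ± 0.11 and a median of -0.23 (adjusted p = 0.00535, and adjusted p = 0.434 with an estimated correlation). The phosphate starvation list had 10 of 16 members lower, 2 higher and 4 not called (the same numbers adjusted over the list alone), with VTC1 at -0.50 ± 0.06 and the phosphatase gene PHM8 higher at 1.15 ± 0.13 (median -0.29, adjusted p = 0.0117, and adjusted p = 0.118 with an estimated correlation). Oxidative phosphorylation genes had 11 of 34 members lower, 1 higher and 22 not called (11 and 0 adjusted over the list alone). CYC1 was at -0.69 ± 0.04 and the list median was -0.13 (adjusted p = 0.0132, and adjusted p = 0.312 with an estimated correlation). The call of this list ended without reference EtOH replicate 3 (median -0.04, adjusted p = 0.0664) and without its chromosome IV members (adjusted p = 0.0862), and its adjusted p lay between 0.0128 and 0.312 over the alternatives. That fit had 13 of its members lower and 2 higher, 1 purine synthesis gene higher and 1 sulfur gene lower.

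The remaining 21 lists were not called in the reference strain (adjusted p from 0.0598 to 0.965). Markers of alpha cells had 0 of 3 tested members called, and markers of meiosis had 8 of 18 higher, 1 lower and 9 not called (median 0.48, adjusted p = 0.0930). The galactose list had 4 of 9 members higher and 1 lower (adjusted p = 0.239), the list of chromosome condensation and H3 S10 phosphorylation had 1 of 14 higher and 2 lower (adjusted p = 0.965), and cohesin and kinetochore genes had 1 of 21 higher and 7 lower (adjusted p = 0.195). In the fit without reference EtOH replicate 3 these numbers were 2 and 5 for condensation, 1 and 12 for cohesin and kinetochore genes, and 7 and 3 for meiosis. Also not called were lists of amino-acid synthesis under Gcn4, ribosome biogenesis, ergosterol, glucose repression, iron, cell wall integrity, the G1/S and G2/M stages, glycolysis, the proteasome, Leu3 targets, hexose transport, the mitotic checkpoint, RNA polymerase II, genes near chromosome ends and genes near the other centromeres. Without reference EtOH replicate 3, the Gcn4 list (adjusted p = 0.0167, and 0.0167 to 0.597 over the alternatives) and the iron list (adjusted p = 0.0306, and 0.0306 to 0.794 over the alternatives) passed. The galactose list (adjusted p = 0.0265, and 0.0265 to 0.375 over the alternatives) and the glucose repression list (adjusted p = 0.0171, and 0.0171 to 0.466 over the alternatives) passed without their chromosome IV members.

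Genes of chromosome IV were raised as a group by E2 in the reference strain. Of 737 tested genes on this chromosome, 66.2% had a fold change above 0, against 47.3% of the other nuclear genes, and 308 were called higher and 99 lower (314 and 104 adjusted over the list alone). Their median log2 fold change lay 0.14 above that of the other nuclear genes, or 10.3%. Among called genes of this chromosome with a mean of at least 10 CPM and no overlap between the libraries, the largest rises were those of BSC1 (YDL037C, IV 384601 to 385587, 2.30 ± 0.22) and PRM7 (YDL039C, IV 381985 to 384081, 2.25 ± 0.23), whose EtOH levels differed between libraries (23, 23.1 and 8.9 CPM for BSC1), followed by YAP6 (1.01 ± 0.08), a transcription factor gene, AAD4 and the endonuclease gene HO (0.94 ± 0.09). HXT6, HXT7, MRK1 (-0.84 ± 0.15), MFA1 and FMP45 (-0.76 ± 0.07) were the lowest of these genes. Camera gave the chromosome an adjusted p of 0.000781 over 16 chromosomes, and 0.000227 with an estimated correlation. The medians of the other 15 chromosomes lay between -0.04 (XVI) and 0.03 (I), and camera called none of them (0 also at an unadjusted p under 0.05). Chromosome IV held 13.0% of the nuclear genes tested and 23.4% of those called higher (Fisher's exact test, odds ratio 2.78, p = 1.97e-33, adjusted p = 3.16e-32), genes not being independent replicates.

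**Figure D1:**
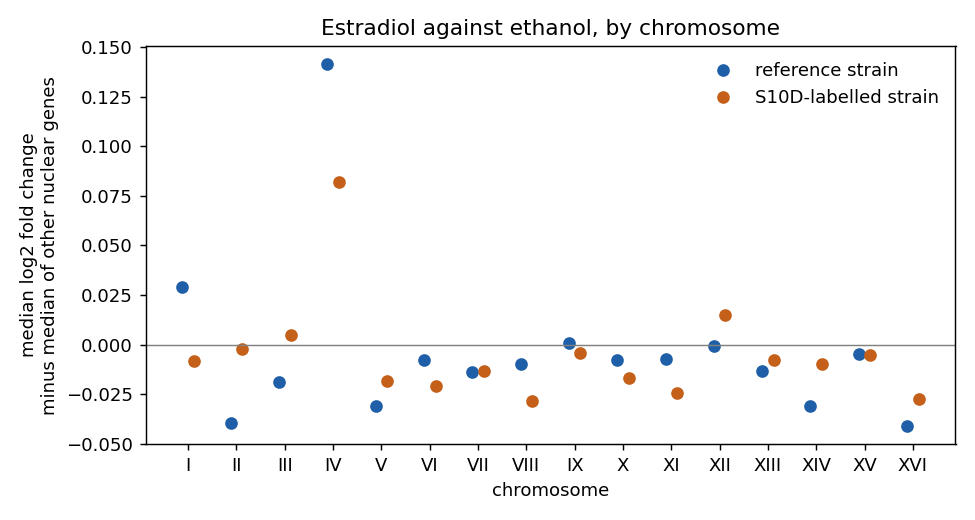
Median log2 fold change of each nuclear chromosome minus the median of all other nuclear genes (vertical axis), for E2 against EtOH in the reference strain (blue points) and in the S10D-labelled strain (orange points). Chromosome IV lies at 0.14 and 0.08, and the other 15 chromosomes lie between -0.04 and 0.03.

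The shift extended over the whole of chromosome IV. In the reference strain its left arm had a median of 0.14 above other genes (225 genes) and its right arm 0.14 (512 genes), and genes within 50 kb of CEN4 had 0.14 (51 genes) against 0.13 (343 genes) beyond 400 kb. The lowest bin, 50 to 100 kb, had 0.07 (42 genes), and the rank correlation with distance across genes was -0.01, genes not being independent replicates. The 51 genes within 50 kb of CEN4, tested as a list, had 20 members higher and 6 lower (the same numbers adjusted over the list alone) and an adjusted p of 0.0406, with an adjusted p = 0.107 with an estimated correlation. Their call also ended without reference EtOH replicate 3 (adjusted p = 0.0581) and with the replicate number as a block (adjusted p = 0.0528), and their adjusted p lay between 0.0408 and 0.107 over the alternatives. In the S10D-labelled strain the arms had medians of 0.08 each, and the list near CEN4 had 1 of 51 members higher and 1 lower (adjusted p = 0.0636), or 8 and 3 without reference EtOH replicate 3. The 50 to 100 kb bin was the lowest there too, at 0.03.

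**Figure D2:**
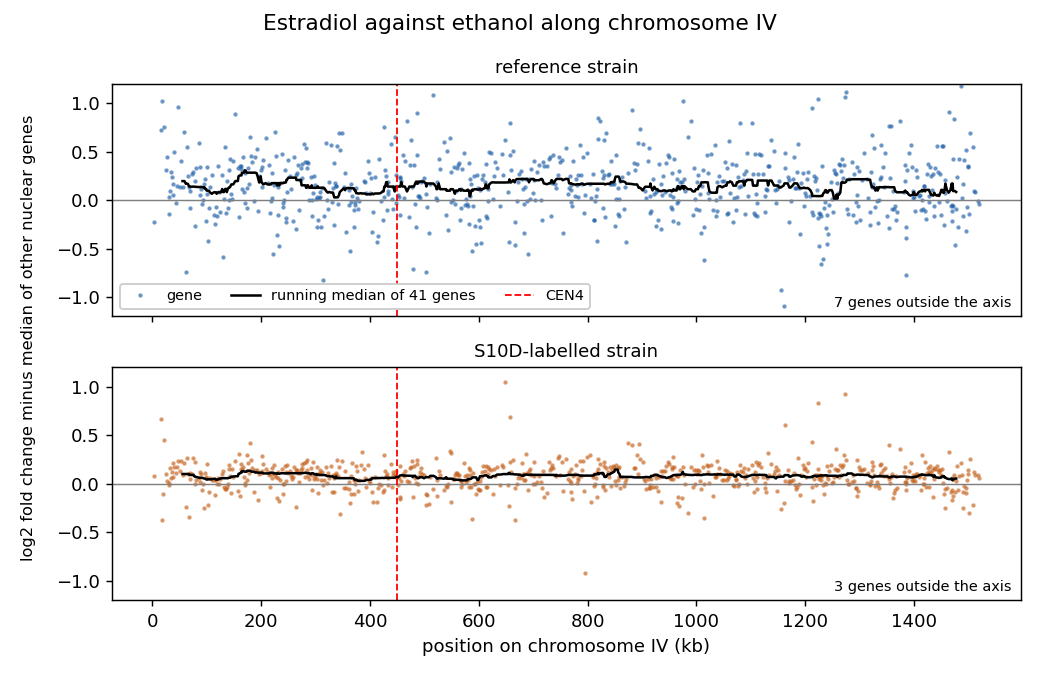
Log2 fold change of each chromosome IV gene, E2 against EtOH, minus the median of the other nuclear genes (vertical axis) against its position in kb, in the reference strain (upper panel) and the S10D-labelled strain (lower panel). Points are genes, the black line is a running median of neighbouring genes and the dashed line marks CEN4, and the running median lies above 0 on both arms.

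The share of nuclear counts on chromosome IV gave a value per library. In the reference strain it was 12.4% ± 0.125 in EtOH and 13.6% ± 0.10 in E2 (SD, n = 3 each), a difference of 1.16 percentage points (exact permutation test, 2-sided, p = 0.1, the smallest that 3 against 3 allows). In the S10D-labelled strain it was 12.6% ± 0.0214 and 13.1% ± 0.0191, a difference of 0.543 points (exact permutation test, 2-sided, p = 0.1). The rise was 0.619 points smaller in the S10D-labelled strain (0.398 without ribosomal protein genes), and the smallest gap between E2 and EtOH libraries was 0.951 points in the reference strain, against a largest gap of 0.574 points in the S10D-labelled strain. Relabelling within strains (exact permutation test, 2-sided, p = 0.26) does not decide whether the rises differ, because relabellings that keep or mirror the groups of a strain retain its rise.

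**Figure D3:**
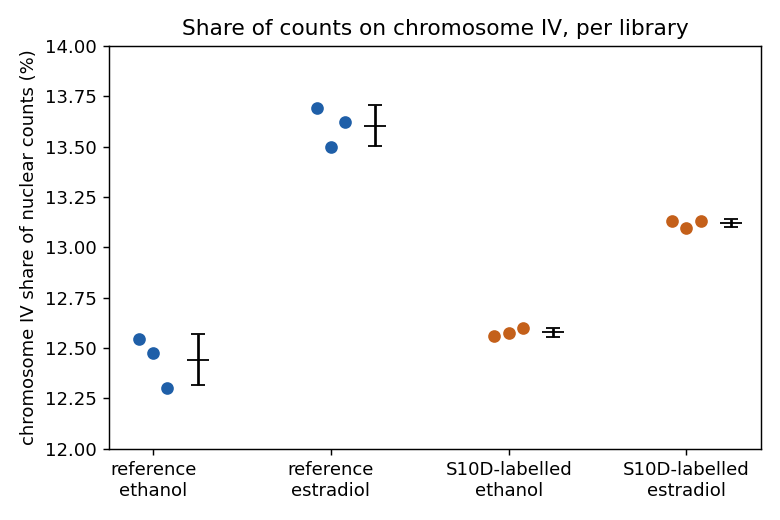
Share of nuclear counts on chromosome IV in percent (vertical axis, which does not start at 0) for the 12 libraries, with the mean and SD of each group beside its 3 points. In both strains each E2 library lies above each EtOH library.

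In the S10D-labelled strain, E2 against EtOH asks the same question beside the histone construct. YNL194C (XIV 272710 to 273615), which encodes an integral membrane protein, rose from 18.4 ± 2.68 to 43.0 ± 2.2 CPM (SD, n = 3), a log2 fold change of 1.23 ± 0.10 (SE), and SHC1 rose by 0.98 ± 0.09. The glucoamylase gene SGA1 rose by 0.78 ± 0.12, INO1 of inositol synthesis by 0.74 ± 0.07 and TSL1 of trehalose synthesis by 0.62 ± 0.08. Genes that fell included the drug transporter gene FLR1 (-0.67 ± 0.05), the transporter gene ATR1 (-0.62 ± 0.05), the oxidoreductase gene OYE3 (-0.58 ± 0.06), the glutathione transferase gene GTT2 (-0.55 ± 0.05) and the nitroreductase genes FRM2 (-0.72 ± 0.10) and HBN1 (-0.70 ± 0.05), while the drug efflux list was not called (median 0.02, adjusted p = 0.53).

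With edgeR, 273 of 5990 genes were called in the S10D-labelled strain, 145 higher and 128 lower, and 4 changed at least 2-fold. With DESeq2 size factors the directions were 116 higher and 165 lower, and with DESeq2 148 and 224. The libraries of both groups did not overlap for 2146 genes (35.8%), where chance gives 10%. The count depends on which libraries were fitted. It was 991 (507 higher, 484 lower) without reference EtOH replicate 3, and 102 to 138 without any 1 of the 6 S10D-labelled libraries. A fit of these 6 libraries alone called 1370 genes, and a fit of the 6 reference libraries alone called 1843. In the shared fit the reference count was 2671, so much of its gap to 273 depends on the shared spread. Of 53 named genes called in this strain, 34 were called without each library in turn and 19 were not (adjusted p up to 0.194), among them PRE3, RPL9B and ERG2 of the lists below.

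Amino-acid synthesis genes under Gcn4 fell in the S10D-labelled strain, with 9 of 28 lower, 0 higher and 19 not called (16 lower adjusted over the list alone). ARG1 (-0.58 ± 0.05), ARG3 (-0.55 ± 0.05) and ARG4 (-0.43 ± 0.06) of arginine synthesis were among them. The list had a median of -0.16 (adjusted p = 1.48e-19, and 0.0330 with an estimated correlation). Of 20 sulfur and methionine genes, 7 fell and 13 were not called (17 lower adjusted over the list alone), including SUL2 (-0.45 ± 0.08), MET3 (-0.35 ± 0.04) and MET16 (-0.34 ± 0.06). Their median was -0.22 (adjusted p = 1.33e-13, and 0.0263 with an estimated correlation). Ribosome biogenesis genes had 8 of 50 higher and 42 not called (20 higher adjusted over the list alone), with UTP20 at 0.50 ± 0.05, a median of 0.11 and an adjusted p of 6.30e-10 (adjusted p = 0.165 with an estimated correlation). Cell wall integrity genes had 4 of 16 higher and 12 not called (6 higher and 2 lower adjusted over the list alone), with the mannoprotein gene CWP1 at 0.42 ± 0.04 and PIR3 at 0.38 ± 0.06 (median 0.11, adjusted p = 0.000248, and adjusted p = 0.343 with an estimated correlation). General stress genes had 3 of 32 higher, 2 lower and 27 not called (6 and 2 adjusted over the list alone), with HSP12 at 0.36 ± 0.04 (median 0.09, adjusted p = 0.00849, and adjusted p = 0.434 with an estimated correlation).

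Lower medians were found in the S10D-labelled strain for ribosomal proteins (1 of 137 lower, also adjusted over the list alone, RPL9B at -0.20 ± 0.04, median -0.08, adjusted p = 6.05e-06, and adjusted p = 0.551 with an estimated correlation). The proteasome list had 1 of 32 lower (9 adjusted over the list alone), PRE3 at -0.21 ± 0.04, and a median of -0.12 (adjusted p = 2.83e-05, and adjusted p = 0.434 with an estimated correlation). Oxidative phosphorylation had 3 of 34 lower (3 adjusted over the list alone), including CYC1 (-0.27 ± 0.04), and a median of -0.06 (adjusted p = 0.00330, and adjusted p = 0.219 with an estimated correlation). Ergosterol synthesis had 2 of 22 lower (2 adjusted over the list alone), ERG4 (-0.23 ± 0.04) and ERG2, and a median of -0.04 (adjusted p = 0.0132, and adjusted p = 0.324 with an estimated correlation). Leu3 targets had 0 of 9 called (2 lower adjusted over the list alone) and a median of -0.09 (adjusted p = 0.0186, and adjusted p = 0.339 with an estimated correlation). The other 24 lists were not called (adjusted p from 0.0636 to 0.989). The numbers of called members depend on the libraries in the shared fit. Without reference EtOH replicate 3, ribosomal proteins had 27 lower and 5 higher, the proteasome list 23 lower and 3 higher, oxidative phosphorylation 6 lower, ergosterol 6 lower and Leu3 targets 4 lower. Gcn4 genes then had 19 lower, sulfur genes 17 lower, ribosome biogenesis 25 higher, cell wall integrity 7 higher and 2 lower, and general stress 10 higher and 4 lower. Glycolysis (adjusted p = 0.0306, and 0.0306 to 0.715 over the alternatives) and heat shock chaperones (adjusted p = 0.0280, and 0.0280 to 0.794 over the alternatives) passed as lists in that fit.

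Chromosome IV genes were raised as a group in the S10D-labelled strain too. Of the 737 genes, 72.2% had a fold change above 0, against 46.8% of the other nuclear genes, with a median 0.08 above theirs, or 5.84%. Camera gave an adjusted p of 1.51e-05 over 16 chromosomes, and 4.75e-05 with an estimated correlation. Of these genes 28 were called higher and 11 lower (29 and 11 adjusted over the list alone), with GIN4, a kinase gene of the bud neck, at 0.31 ± 0.06, and MTH1 (-0.36 ± 0.04) and AAD4 (-0.38 ± 0.05) among the lowest. Chromosome IV held 28 of 142 nuclear genes called higher (Fisher's exact test, p = 0.0222, adjusted p = 0.355), but without reference EtOH replicate 3 it held 141 of 498 (28.3%, odds ratio 3.03, adjusted p = 1.51e-20) and 38 of 479 called lower. The other 15 chromosomes had medians from -0.03 (VIII) to 0.01 (XII), and camera called none (at an unadjusted p under 0.05, 0 with the preset and 4 with the estimated correlation).

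The difference of the responses tests whether E2 acted differently in both strains. FRM2 rose by 1.46 ± 0.23 in the reference strain and fell in the S10D-labelled strain, a difference of -2.18 ± 0.25. Its reference levels were near the floor, at 1 to 1.3 CPM in EtOH and 2.7 to 3.6 in E2, against 18.9 to 37.3 in S10D-labelled libraries. PRM7 (-2.06 ± 0.31), BSC1 (-1.97 ± 0.29), CYC7 (-1.65 ± 0.15), HXT5 (-1.52 ± 0.15) and SHC1 (-1.51 ± 0.12), which rose in the reference strain, had lower responses in the S10D-labelled strain. In its EtOH libraries PRM7 (242.9 to 263.2 CPM) and BSC1 (103.9 to 110.4) already stood above their reference E2 levels (210.7 to 222.7 and 87.2 to 90.5). CYC7 had 105.2 to 118.5 CPM there, against 27.6 to 41.4 in reference EtOH and 139.4 to 153.8 in reference E2. HXT5 (12.9 to 16.7 CPM) and SHC1 (9.3 to 9.9) were low there. SPL2 (1.45 ± 0.26), HMS2 (0.89 ± 0.08) and the iron oxidase gene FET3 (0.85 ± 0.07), which fell in the reference strain, had higher responses. SPL2 had only 2.3 to 4.2 CPM in the S10D-labelled libraries, which leaves its response there uncertain. Among called genes with a mean of at least 10 CPM, SCR1 had the largest positive difference (2.24 ± 0.70, adjusted p = 0.0497), and leaving out any of 8 of the 12 libraries in turn ended its call (adjusted p up to 0.117, and 0.00585 to 0.117 over the alternatives). Its levels in the S10D-labelled E2 libraries were uneven (38.9, 19.7 and 14.9 CPM).

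With edgeR, the response of 1224 of 5990 genes differed, 588 higher and 636 lower in the S10D-labelled strain, and 79 differed at least 2-fold (8 higher, 71 lower). Without reference EtOH replicate 3 the count was 1994 (992 higher, 1002 lower). Across genes, the responses had a Pearson correlation of 0.26 and a Spearman correlation of 0.36, with a slope of 0.14 of the S10D-labelled on the reference response, genes not being independent replicates. Of the genes called higher in the reference strain, 125 were also called higher in the S10D-labelled strain, where independent lists would share 32.5 (Fisher's exact test, p = 1.02e-61), and 50 were called lower in both, against 28.4 (p = 1.29e-05). The 43 genes called higher in the reference and lower in the S10D-labelled strain, against 28.7 in independent lists, included FRM2, HSP26, AAD4, SUL2 and MET3. In the other direction, 2 genes were called lower in the reference and higher in the S10D-labelled strain, against 32.2 in independent lists.

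**Figure D4:**
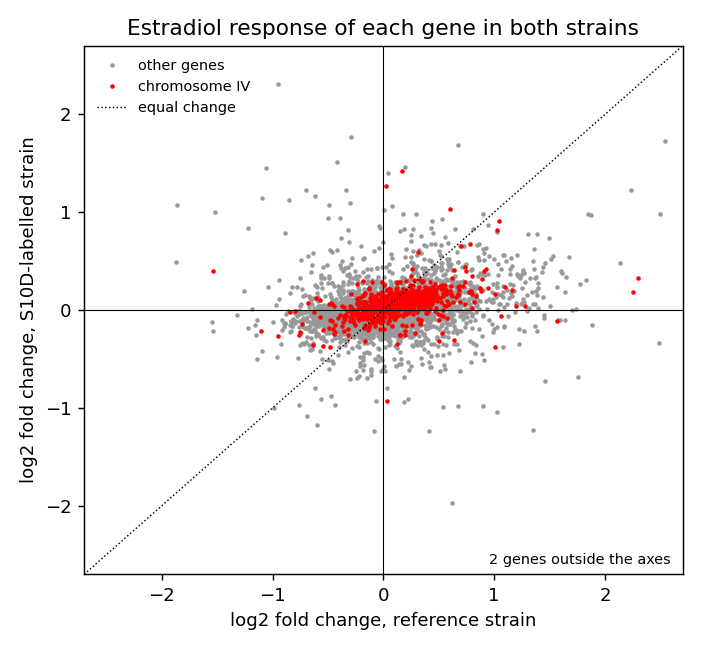
Log2 fold change of each tested gene, E2 against EtOH, in the S10D-labelled strain (vertical axis) against that in the reference strain (horizontal axis), with chromosome IV genes in red, other genes in grey and a dotted line of equal change. The points spread along the horizontal axis, with a slope of 0.14 across genes.

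Ribosomal protein genes had higher responses in the S10D-labelled strain, with 112 of 137 different (122 adjusted over the list alone), none the other way and a median difference of 0.45 (adjusted p = 2.42e-53, and adjusted p = 0.0553 with an estimated correlation). Sulfur and methionine genes had the largest median difference, with 16 of 20 lower and 4 not called (18 lower adjusted over the list alone), led by STR3 (-1.56 ± 0.14) and SUL2 (-1.35 ± 0.14), and a median of -0.78 (adjusted p = 8.40e-32, and 0.00376 with an estimated correlation). General stress genes had 23 of 32 lower and 9 not called (24 lower and 2 higher adjusted over the list alone). CTT1 was at -1.46 ± 0.08 and the list median was -0.74 (adjusted p = 1.98e-31, and 0.0117 with an estimated correlation). Heat shock chaperone genes had 13 of 21 lower (14 adjusted over the list alone). SSA4 was at -1.21 ± 0.08 and the list median was -0.37 (adjusted p = 2.08e-15, and adjusted p = 0.126 with an estimated correlation). Gcn4 genes had 14 of 28 lower and 1 higher (17 and 2 adjusted over the list alone). The amino-acid permease gene AGP1 was at -0.98 ± 0.10 and the list median was -0.30 (adjusted p = 1.05e-09, and adjusted p = 0.108 with an estimated correlation).

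Smaller lists also had different responses. Core histone genes had 6 of 8 higher (6 adjusted over the list alone). HTA2 was at 0.66 ± 0.11 and the list median was 0.48 (adjusted p = 0.000127, and adjusted p = 0.316 with an estimated correlation). M/G1 daughter-cell genes had 7 of 13 higher (8 higher and 1 lower adjusted over the list alone). CTS1 was at 0.50 ± 0.06 and the list median was 0.29 (adjusted p = 0.000109, and adjusted p = 0.0553 with an estimated correlation). DNA damage genes had 7 of 16 lower (8 adjusted over the list alone). RAD16 was at -0.66 ± 0.09 and the list median was -0.22 (adjusted p = 0.00126, and adjusted p = 0.0553 with an estimated correlation). Drug efflux genes had 4 of 12 lower (5 adjusted over the list alone). SNQ2 was at -0.78 ± 0.08 and the list median was -0.18, which stood at -0.11 without reference EtOH replicate 3 (adjusted p = 0.00251, and adjusted p = 0.332 with an estimated correlation). Purine synthesis genes had 5 of 10 higher (5 adjusted over the list alone). ADE17 was at 0.47 ± 0.09 and the list median was 0.24, which stood at 0.16 without that library (adjusted p = 0.0103, and adjusted p = 0.432 with an estimated correlation). The phosphate list had 6 of 16 higher and 1 lower (8 and 1 adjusted over the list alone). GIT1 was at 0.84 ± 0.17 and the list median was 0.29 (adjusted p = 0.0178, and adjusted p = 0.126 with an estimated correlation), and its call ended without that library (adjusted p = 0.0679, and 0.00634 to 0.126 over the alternatives). The other 24 lists were not called (adjusted p from 0.0506 to 0.932). Without reference EtOH replicate 3, the list of a cells and pheromone response passed (15 higher and 1 lower, against 7 and 1 with it; median 0.25 against 0.15; adjusted p = 0.000534, and 0.000534 to 0.597 over the alternatives). The iron list (adjusted p = 0.00276, and 0.00276 to 0.6003 over the alternatives) and the proteasome list (adjusted p = 0.0129, and 0.0129 to 0.8525 over the alternatives) passed too. In that fit heat shock chaperones had 19 lower and 1 higher, Gcn4 genes 19 lower and 2 higher, M/G1 daughter-cell genes 10 higher and 1 lower, and purine synthesis genes 5 higher and 1 lower.

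Chromosome IV genes had a lower median response in the S10D-labelled strain, with 34 genes different upward and 120 downward (36 and 124 adjusted over the list alone) and a median difference of -0.07. These numbers were 64 and 172 without reference EtOH replicate 3. The other 15 chromosomes lay between -0.06 (I) and 0.03 (II), so chromosome I was about as low. Camera gave an adjusted p of 0.383 over 16 chromosomes (0.0166 with an estimated correlation) and an adjusted p of 0.0598 over the lists. Chromosome IV held 120 of 632 nuclear genes with a lower response (Fisher's exact test, odds ratio 1.68, adjusted p = 9.28e-05) and 34 of 575 with a higher response (odds ratio 0.392, adjusted p = 1.50e-07). Fisher's test treats genes as independent. Chromosome IV was enriched among genes called higher in the reference strain. Fisher's test therefore does not separate this chromosome from the weaker response of the S10D-labelled strain. In camera with an estimated correlation the adjusted p over the lists was 0.0162, and without reference EtOH replicate 3 it was 0.0490 (0.0162 to 0.0748 over the alternatives).

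The S10D-labelled against the reference strain in EtOH compares genotypes that differ at many labelled loci besides the histone. The lists of sulfur and amino-acid genes were higher in the S10D-labelled strain, and those of phosphate and purine genes were lower. The oxidoreductase gene OYE3 (YPL171C, XVI 226169 to 227371) was at 6.45 ± 1.27 CPM in the reference and 1070.0 ± 0.160 CPM in the S10D-labelled strain (SD, n = 3), a log2 fold change of 7.36 ± 0.09 (SE). ARG3 was higher by 5.08 ± 0.07, the zinc transporter gene ZRT1 by 4.89 ± 0.07 and ATR1 by 4.48 ± 0.06. QDR2 (-4.43 ± 0.09), PHM6 (-4.58 ± 0.20), SPL2 (-3.84 ± 0.16) and ADE17 (-3.41 ± 0.07) were lower. YBR013C had 703 counts over the 3 reference EtOH libraries and 1 in the S10D-labelled, 651-fold lower for depth (95% counting interval 116 to 25741), and AIF1 had 1516 and 5, 281-fold lower (120 to 866).

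With edgeR, 3481 of 5990 genes were called between the strains, 1602 higher and 1879 lower, 546 of them at least 2-fold (267 higher, 279 lower). The libraries did not overlap for 3656 genes (61.0%), where chance gives 10%. Chromosome IV did not differ as a group, with 206 genes higher and 221 lower and a median 0.01 above other genes (camera adjusted p = 0.83 over the lists). RPL38 was called lower at -1.06 and stood at -0.30 without reference EtOH replicate 3.

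All 20 sulfur and methionine genes were higher in the S10D-labelled strain (20 adjusted over the list alone), led by SUL2 (3.40 ± 0.10), with a median of 1.82 (adjusted p = 1.42e-40, and 0.00285 with an estimated correlation). The reference strain lacks MET17, which makes homocysteine from sulfide. Of 28 Gcn4 genes, 24 were higher, 1 lower and 3 not called (24 and 1 adjusted over the list alone). The list median was 0.82 (adjusted p = 1.03e-22, and 0.0162 with an estimated correlation). Purine synthesis genes had 9 of 10 lower and 1 not called (9 adjusted over the list alone). ADE2 was at -1.99 ± 0.07 and the list median was -1.28 (adjusted p = 3.03e-15, and 0.0428 with an estimated correlation). The phosphate list had 13 of 16 lower and 3 not called (13 adjusted over the list alone). The transporter gene PHO84 was at -2.65 ± 0.09 and the list median was -0.88 (adjusted p = 8.16e-08, and 0.00963 with an estimated correlation). Mating genes of a cells had 20 of 23 lower and 2 higher (the same numbers adjusted over the list alone). FUS1 was at -2.33 ± 0.08 and the list median was -0.82 (adjusted p = 1.77e-07, and adjusted p = 0.186 with an estimated correlation). With reference EtOH replicate 3 left out, 1 of these mating genes and 1 phosphate gene were higher.

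Further lists differed between the strains with the preset correlation alone. Leu3 targets had 8 of 9 higher (8 adjusted over the list alone). LEU1 was at 1.68 ± 0.05 and the list median was 1.03 (adjusted p = 3.63e-07, and adjusted p = 0.0553 with an estimated correlation). Ergosterol genes had 19 of 22 higher (19 adjusted over the list alone). ERG13 was at 1.12 ± 0.04 and the list median was 0.50 (adjusted p = 5.16e-07, and adjusted p = 0.0553 with an estimated correlation). The proteasome list had 31 of 32 higher (31 adjusted over the list alone). RPN9 was at 0.90 ± 0.08 and the list median was 0.53 (adjusted p = 5.69e-07, and adjusted p = 0.343 with an estimated correlation). Heat shock chaperones had 18 of 21 higher and 1 lower (19 and 1 adjusted over the list alone). STI1 was at 1.08 ± 0.06 and the list median was 0.67 (adjusted p = 2.19e-06, and adjusted p = 0.343 with an estimated correlation). Oxidative phosphorylation had 22 of 34 higher and 2 lower (the same numbers adjusted over the list alone). RIP1 was at 0.95 ± 0.04 and the list median was 0.29 (adjusted p = 0.000102, and adjusted p = 0.103 with an estimated correlation). Ribosomal proteins had 121 of 137 lower and 2 higher (122 and 2 adjusted over the list alone). RPS12, whose reference EtOH level was highest in replicate 3, was at -1.33 ± 0.18 and the list median was -0.33 (adjusted p = 8.77e-08, and adjusted p = 0.454 with an estimated correlation). General stress genes had 17 of 32 lower and 4 higher (the same numbers adjusted over the list alone), and 17 and 9 without reference EtOH replicate 3. SIP18 was at -3.48 ± 0.11 and the list median was -0.47, which stood at -0.30 without that library (adjusted p = 9.55e-05, and adjusted p = 0.309 with an estimated correlation). The iron list had 12 of 22 lower and 4 higher (13 and 4 adjusted over the list alone). FET3 was at -1.88 ± 0.05 and the list median was -0.47 (adjusted p = 0.00489, and adjusted p = 0.434 with an estimated correlation). M/G1 daughter-cell genes had 9 of 13 lower and 2 higher (the same numbers adjusted over the list alone). DSE1 was at -1.15 ± 0.05 and the list median was -0.40 (adjusted p = 0.00535, and adjusted p = 0.126 with an estimated correlation). Genes of G1/S had 22 of 27 lower and 1 higher (the same numbers adjusted over the list alone). CLN1 was at -0.79 ± 0.09 and the list median was -0.35 (adjusted p = 0.00849, and adjusted p = 0.343 with an estimated correlation). The other 20 lists were not called (adjusted p from 0.0545 to 0.932). Core histone genes passed as lower without reference EtOH replicate 3 (adjusted p = 0.0261, and 0.0167 to 0.597 over the alternatives). Their median was -0.07 in that fit, with 3 members higher and 4 lower. This list includes HHF2 and HHT2, which the construct replaces, so its call does not speak for the other histone genes. In that fit 1 ergosterol gene and 1 proteasome gene were lower. In no called list of any comparison did the median, the mean and the test differ in sign.

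**Figure D5:**
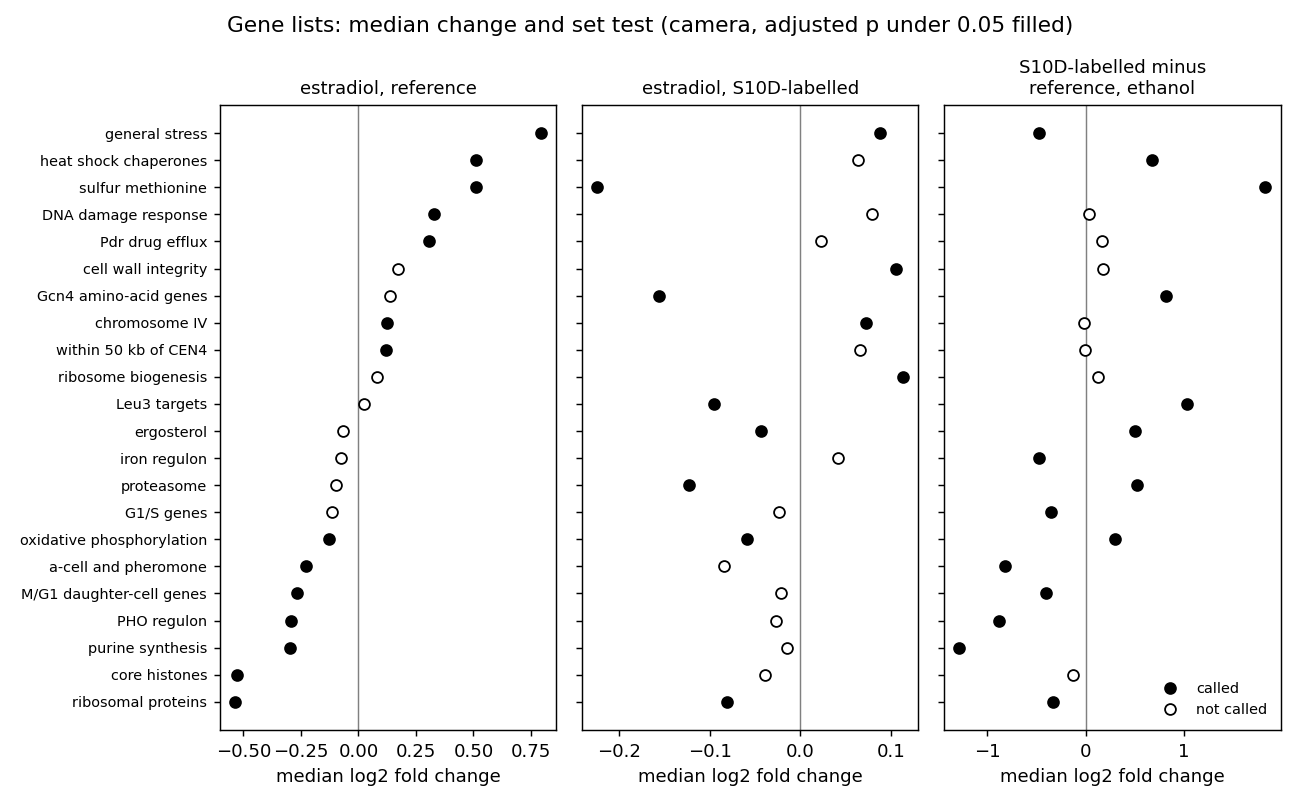
Median log2 fold change (horizontal axes, with a scale of their own in each panel) of the gene lists called in at least 1 of the comparisons shown, for E2 against EtOH in both strains and for the S10D-labelled minus the reference strain in EtOH. Filled points passed camera at the preset correlation (14, 11 and 15 of 35 lists) and open points did not; ribosomal protein genes have the lowest and general stress genes the highest median in the reference response.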

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

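The ratio of spreads of the responses, the number of genes that differ between the strains, the comparison of chromosome arms, the medians with different EtOH libraries and the gap between libraries in the share without abundant genes were tests chosen after the result was seen; the share itself and the other tests in this part were fixed before. The results here drew attention because the responses of the S10D-labelled and the reference strain to E2 were compared. In edgeR, 1224 genes differed in response. When the libraries of each strain were regrouped at random, 7 of 100 drawn splits, the real one included, called as many genes, and the highest other split called 1586. The 10 drawn splits that kept or mirrored the reference grouping called 1055 to 1586 genes, 6 of them as many as the real one, and the 89 that regrouped the reference libraries called 0 to 7. Splits of the first kind still hold the whole reference response, so these splits do not decide whether chance is excluded. Without reference EtOH replicate 3 the count was 1994.

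Gene groups differed in response by these median log2 values, S10D-labelled minus reference. Sulfur and methionine genes had -0.78, general stress genes -0.743, heat shock chaperones -0.371, Gcn4 genes -0.300, DNA damage genes -0.215 and drug efflux genes -0.176. With an estimated correlation the first 2 kept their call (adjusted p = 0.00376 and 0.0117) and the other 4 lost it (adjusted p = 0.126, 0.108, 0.0553 and 0.332). Core histone genes had 0.479, ribosomal protein genes 0.446, M/G1 daughter-cell genes 0.289, phosphate genes 0.289 and purine synthesis genes 0.243. All 5 lost their call with an estimated correlation (adjusted p = 0.316, 0.0553, 0.0553, 0.126 and 0.432). Without reference EtOH replicate 3, drug efflux stood at -0.11, purine synthesis at 0.16 and the phosphate list was not called (adjusted p = 0.0679, and 0.00634 to 0.126 over the alternatives). The chromosome IV median lay -0.0695 from that of other genes, which camera did not call (adjusted p = 0.383 over 16 chromosomes, and 0.0598 over the lists). It was called with an estimated correlation (adjusted p = 0.0166 and 0.0162), and over the lists without reference EtOH replicate 3 (adjusted p = 0.0490).

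Single genes differed in response by these log2 values. The RNAs SCR1 (2.243), snR17a (1.928) and snR81 (0.892), the ribosomal protein genes RPL42B (1.046), RPS12 (1.037) and RPS28B (1.006), and SPL2 (1.455), HXT6 (0.896), HMS2 (0.892) and FET3 (0.846) had higher values in the S10D-labelled strain. In its E2 libraries SCR1 stood at 38.9, 19.7 and 14.9 CPM and snR17a at 33.1, 16.6 and 13.1, highest in replicate 1. For snR81 they had 6.5, 5.3 and 7.3 CPM. Whether more RNA without a poly(A) tail entered that replicate 1 was not tested. RPL42B, RPS12 and RPS28B had their highest reference EtOH level in replicate 3, the library that stands apart (RPS12 4389 CPM against 2796 and 2435). FRM2 (-2.184), PRM7 (-2.063), BSC1 (-1.974), YER053C-A (-1.672), CYC7 (-1.653), YCL048W-A (-1.6), STR3 (-1.565), HXT5 (-1.518), YOR338W (-1.515) and SHC1 (-1.512) had lower values. In S10D-labelled EtOH libraries FRM2, PRM7, BSC1, YER053C-A, STR3 and YOR338W already stood above their reference E2 levels. CYC7, YCL048W-A, HXT5 and SHC1 did not. Of 40 other named genes of the E2 comparisons, 26 differed in response. The calls of SCR1, snR81, HXT6 and RPS28B ended when some of the libraries were left out in turn (adjusted p up to 0.117, 0.0974, 0.102 and 0.0599).

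The weaker response of the S10D-labelled strain could be technical. Hidden changes of equal size under a larger spread are argued against, since the interquartile range of fold changes outside chromosome IV was 0.427 of that in the reference strain (0.151 against 0.353). The EtOH library that stands apart is argued against as the cause, since the ratio was 0.431 without it. That library was itself picked after the data were seen. It stays open whether genes raised in the reference strain were already high in the S10D-labelled strain: their median difference between strains in EtOH was 0.132, but this value shares its EtOH libraries with the response (genes called lower had -0.218). When the response and the strain difference took different reference EtOH libraries, genes with a response above 0.2 had medians of 0.0265 to 0.134 and genes below -0.2 had -0.278 to -0.0953. The sign was kept, but medians of the genes above 0.2 lay on both sides of the bounds set before. They were 0.107 to 0.134 when the response took EtOH replicate 1 or 2, above the bound set for this explanation. They were 0.0361 and 0.0265, under the bound set against it, when the response took replicate 3, the library that stands apart. The histone construct cannot be told apart from the other strain differences, because 3481 genes differed in EtOH and no strain differs by the construct alone. Excision of CEN4 was not measured either, so whether it was alike in both strains is unknown.

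The rise of chromosome IV genes after E2 in both strains could come from gene features, from a few abundant genes or from more DNA. Gene length, GC content and expression level are argued against, since removing their trends left medians of 0.166 in the reference (0.141 before) and 0.0827 in the S10D-labelled strain (0.0818 before). A few abundant genes are argued against, since without the 50 features with most counts the lowest E2 library still lay 1.207 percentage points above the highest EtOH library of the reference strain. More chromosome IV DNA per cell stays open: both arms moved alike (right minus left 0.00634), which any effect on the whole chromosome would give, and no DNA was measured. An effect of E2 or Cre apart from the loss of CEN4 stays open as well, as untested.

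For the other counts of genes called, the 10 splits of 6 libraries into groups of 3 are too few for a share under 0.05. The real split called 2671 genes in the reference strain, 273 in the S10D-labelled strain and 3481 between the strains. Each was the 1 split of 10 with as many, and the highest other split called 0 in each. Every other split mixes both groups, so the real differences enter its spread, and the 0 calls do not argue against chance.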

How the results depend on the processing

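The fits without reference EtOH replicate 3 for the S10D-labelled response, the gene lists and chromosome IV among called genes, and the estimated correlation for the chromosome IV median, were chosen after the result was seen. No gene or list called in a fit was called with the other sign under any alternative. Medians of some lists that were not called changed sign without reference EtOH replicate 3, such as Leu3 targets in the reference strain (0.0240 to -0.0773) and glycolysis there (-0.0591 to 0.00628). At an absolute log2 fold change of at least 1, 129 of 2671 genes stayed called in the reference strain, 4 of 273 in the S10D-labelled strain, 79 of 1224 for the difference and 546 of 3481 between the strains, because the threshold is stricter. Fitting only the 6 libraries compared called 1843 genes in the reference strain, 1370 in the S10D-labelled strain and 2922 between the strains. In the S10D-labelled strain, leaving out 1 library at a time called 102 to 991. The 991 came without reference EtOH replicate 3, which is not compared here but enters the shared spread, filter and scaling. The same ranges were 2133 to 3133 in the reference strain, 906 to 1994 for the difference and 3127 to 3935 between the strains, the highest value each time without reference EtOH replicate 3. All 273 S10D-labelled calls and 1213 of the 1224 differences were kept without that library. DESeq2 called 2540, 372, 1197 and 3361 genes, and edgeR without a filter 2609, 251, 1181 and 3490. The replicate number as a block called 2679, 233, 1212 and 3504 genes. Deviations of same-numbered libraries correlated at 0.0873, 0.0711 and 0.00223 in the reference and 0.0676, 0.126 and -0.002 in the S10D-labelled strain. Replicates 1 and 2 correlated best with their own number and replicate 3 did not, so the numbers were not taken to pair the samples. Over all alternatives the chromosome IV median lay between 0.136 and 0.145 in the reference strain and between 0.0740 and 0.0849 in the S10D-labelled strain, and its difference between -0.0749 and -0.0596 (camera p 0.00104 to 0.0374 before adjustment). The difference of the chromosome IV shares lay between -0.773 and -0.398 points. Of 692 values of gene lists under alternatives, 629 kept their side of the threshold, 41 lost it (most of them under the estimated correlation) and 22 gained it. Of the gains, 9 came without reference EtOH replicate 3, 7 without chromosome IV members, 4 with the replicate block, 1 with DESeq2 size factors and 1 with the estimated correlation. Without chromosome IV members they were the galactose and glucose repression lists in the reference strain (adjusted p = 0.0265 and 0.0171) and for the difference (0.0167 and 0.0146), glycolysis in the S10D-labelled strain (0.0327), iron for the difference (0.0207) and core histones between the strains (0.0167). With the block they were glycolysis (0.0427), iron (0.0373), core histones (0.0393) and, for the difference, genes of a cells (0.0390, and 0.0470 with DESeq2 size factors). The core histone list includes HHF2 and HHT2, which the construct replaces in the S10D-labelled strain. Of 4347 values of named genes, 4121 kept it, 178 lost it and 48 gained it. Without single libraries, LEU2 (adjusted p up to 0.0790) was, among named genes, the call between the strains that was lost, beside 2 in the reference strain, 19 in the S10D-labelled strain and 7 for the difference; the cause was not tested. At this depth 28 of 49 simulated changes of the smallest size were recovered over genes of all levels, and other depths were not simulated.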

Other observations

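The tests of the coding length of reference EtOH replicate 3 and of its SCR1 and 21S_RRNA levels were chosen after the result was seen. So was the test of the chromosome XIV stretch. The others were fixed before their own results, but reference EtOH replicate 3 was itself picked after the data were seen. The galactose, glucose repression and hexose transport lists were not called in the reference strain (adjusted p = 0.239, 0.216 and 0.83), and single members changed. SIP4, a regulator of gluconeogenesis, rose by 1.74 ± 0.21 (log2, SE, n = 3 per group) after E2, GAL7 of galactose use by 0.81 ± 0.14 and the glycerol dehydrogenase gene GCY1 by 0.80 ± 0.05, while MTH1, a repressor of hexose transporter genes, changed by -0.63 ± 0.04. In the S10D-labelled strain MTH1 changed by -0.36 ± 0.04 and GCY1 by -0.18 ± 0.04, and the call of GCY1 ended without each of 6 libraries in turn (adjusted p up to 0.159). Among genes of chromosome segregation in the reference strain, the cohesin loader gene SCC2 on chromosome IV rose by 0.79 ± 0.06, and the kinetochore gene NSL1 (-0.49 ± 0.06) and the centromeric histone gene CSE4 (-0.31 ± 0.06) fell.

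The iron list was not called for E2 in the reference strain (adjusted p = 0.245) or in the S10D-labelled strain (adjusted p = 0.286), and members went both ways: 6 of 22 rose and 9 fell in the reference strain, and 2 rose and 2 fell in the S10D-labelled strain (4 and 3 without reference EtOH replicate 3). It passed in the reference strain without reference EtOH replicate 3 (adjusted p = 0.0306, and 0.0306 to 0.794 over the alternatives). The oxidase gene FET3 changed by -0.86 ± 0.05 and its partner permease gene FTR1 by -0.64 ± 0.07 after E2 in the reference strain, and the cell wall mannoprotein gene FIT1 by 0.68 ± 0.11. In the S10D-labelled strain the siderophore transporter gene SIT1 rose by 0.61 ± 0.08 and the low-affinity iron transporter gene FET4 by 0.45 ± 0.07, while the heme oxygenase gene HMX1 fell by 0.30 ± 0.07, a call that ended without each of 5 libraries in turn (adjusted p up to 0.118). Between the strains in EtOH, HMX1 was higher in the S10D-labelled strain by 2.84 ± 0.08 and FET4 lower (-2.42 ± 0.07).

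Reference EtOH replicate 3 stood apart from its group, which could reflect library preparation or another state of its culture. A bias with coding length as the whole cause is argued against, since the trend removed 8.05% of the variance of its deviations. More RNA without a poly(A) tail is argued against for snoRNA and snRNA features, whose median deviation was -0.119. It stays open for SCR1 and 21S_RRNA, at least 1.269 (log2) above the other libraries of the group, features picked because they stand out. Another growth state stays open too, since general stress genes deviated by 0.152 after the length trend was removed, between the bounds set for and against it.

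At the right end of chromosome XIV (765375 to 778738), genes had few or no counts in the S10D-labelled strain, and those named here were chosen after their values were seen. Over 6 libraries each, PDR18 had 344 counts in the reference and 0 in the S10D-labelled strain, YNR071C 339 and 1, and AIF1 3098 and 7, while the neighbours BSC5 and COS10 kept 59.8% and 23.7% of their reference counts for depth. A candidate explanation is that the S10D-labelled strain lacks this stretch. The low neighbours HXT17 and MAN2 within it had 0 counts together against 172 in the reference strain.

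Chromosome IV responses of both strains correlated at 0.486 across genes, above each of the other 15 chromosomes (highest 0.391, chromosome IX), genes not being independent replicates. A dependence of the shift on expression level is argued against, since the rank correlation with mean CPM on chromosome IV differed from that of other genes by 0.0422.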
